A study of Mus musculus with 20 samples.

How the data were processed

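Expression was measured in mammary glands of 20 female FVB/N mice heterozygous for a transgene that drives transforming growth factor alpha (TGFα) in the mammary gland, with 1 array per animal. The labels place a subcutaneous implant at 8.5 weeks of age, with 5 mg tamoxifen or no drug (placebo), and removal of a tumor-free number 4 gland at 20.5 to 21 weeks, 4 weeks after treatment ended. Animals were then watched for mammary tumors until at most 2 years of age. Total RNA was copied to biotin-labelled cRNA and read on Affymetrix arrays, per the labels. Each array was assigned to its treatment and its later tumor outcome from the labels.

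The deposited values are RMA expression per probe set on the log2 scale, made by the authors with RMA per the submitters' processing notes. The software, its version and the genome build are not given in the sources used here. The 45101 probe sets had values from 3.38 to 14.55, and array medians lay between 6.82 and 6.89. No pair of arrays was identical, and pairwise Pearson correlations ran from 0.977 to 0.997. The values were used as they stood. For these arrays, their number limits the precision.

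Probe sets were joined to gene symbols with the platform table. Probe sets with 1 symbol numbered 34958, of which 34754 were matched to a current symbol by Entrez ID, while 932 with several symbols and 9211 with none were left out of the gene-wise tests. Each of 18193 genes was represented by its probe set with the highest mean over the 20 arrays. Genes were tested when their values exceeded the median of all values (6.85) on at least 3 arrays, which left 12498.

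Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust settings), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. There were 8 gene-wise comparisons. Tumor was compared with no tumor, and tamoxifen with placebo, each alone and adjusted for the other factor. A model of the 4 groups gave the outcome difference within placebo animals, that within tamoxifen animals, their interaction, and tamoxifen animals without tumors against placebo animals with tumors. The correlation across genes of the outcome differences in placebo and tamoxifen animals was tested with 100 draws of the outcome labels within treatments. In the 8 comparisons, fold changes are 2 to the power of the absolute log2 difference. Spreads are SD and errors of differences are SE.

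Lists of genes were tested by the mean, per animal, of the gene-wise centred log2 values of all list genes with a probe set. Labels were permuted with 100000 resamples, or by the exact test of 3432 arrangements for 7 against 7 animals, two-sided, with adjustment over the 25 lists. The lists were luminal progenitor, mature luminal, pan-epithelial and luminal keratin, basal and myoepithelial, milk and alveolar, oestrogen and progesterone response, epidermal growth factor (EGF) receptor family and ligands, cell division, p53 targets, white adipocyte, brown adipocyte, fatty acid synthesis, B cell, T cell, plasma cell, macrophage, interferon response, fibroblast and matrix, endothelial, skeletal muscle, Schwann cell, epidermis, blood, immediate early, and circadian clock genes. Of 275 listed genes, 254 had a probe set with a matching symbol. Genes without one, Prlr, Areg, Ccnb1 and Plin1 among them, are not analysed here. Members were counted by limma over all genes tested and adjusted over the list alone. camera with a preset correlation of 0.01 and with an estimated correlation served as alternatives.

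The groups, comparisons, filters, lists, named-gene rule and most other settings were fixed before the data were examined. Named genes were the 12 largest positive and 12 largest negative log2 differences past the threshold in the outcome, treatment and 7-against-7 comparisons. Where fewer than 10 genes passed, those with the smallest p were added until 10 were named, as values that did not pass. In the other comparisons the 3 largest in each direction, or the 3 smallest p where none passed, were named. Up to 4 members were taken per list by their moderated statistic. A set that included Tgfa, Esr1, Pgr, Kit, Elf5, Krt14, Krt18, Mki67, Adipoq and Ckm was given whether or not its genes passed.

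Other settings tried, and fixed in the same way, covered array scaling, the filter on dim probe sets, the choice of probe set, the variance model, array weights, blocks for the replicate numbers and for the 2 runs of numbers 1 to 5 and 6 to 10, and leaving out each animal. Chosen after seeing the data were fits without the 2 or 3 animals farthest on the first principal component, fits with the skeletal muscle or pan-epithelial list mean as a covariate, and list tests within treatments or outcomes. The closing section gives their effects.

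The gene-wise procedure was tested on simulated data of 12498 genes with the same numbers of arrays and 100 genes changed at each of 2 sizes. A change of 1 on the log2 scale was called in 98% of those genes for tumor against no tumor and in 90% for the interaction. Of 500 unchanged simulated lists, 5.6% had a permutation p under 0.05. Each gene's noise was drawn independently from a normal distribution, with no outlying animals and no correlation between genes. The simulated lists were per-animal values drawn in the same way. These rates therefore hold for such noise and do not give the power on the real arrays.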

Results

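Gene expression was measured on 20 arrays, each from 1 tumor-free mammary gland of a mouse carrying a TGFα transgene, and each animal was later scored for mammary tumors. TGFα is a growth factor that binds the EGF receptor, and tamoxifen is a selective oestrogen receptor modulator. Of 10 placebo animals, 7 later had a tumor and 3 did not, and of 10 tamoxifen animals, 3 had a tumor and 7 did not. Among these sampled animals the share with a tumor gave a two-sided Fisher's exact p of 0.179 between treatments. Animals are named by treatment and replicate number. The number of arrays limits the precision of every value, and no comparison draws on more than 1 array per animal.

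On the first 2 principal components, which held 31.9% and 13.65% of the variance, most arrays formed 1 cloud. Placebo animals 8, 7 and 9, all with later tumors, lay farthest out on the first component, at -41.13, -30.94 and -14.64, and the next farthest array was at 12.65.

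**Figure D1:**
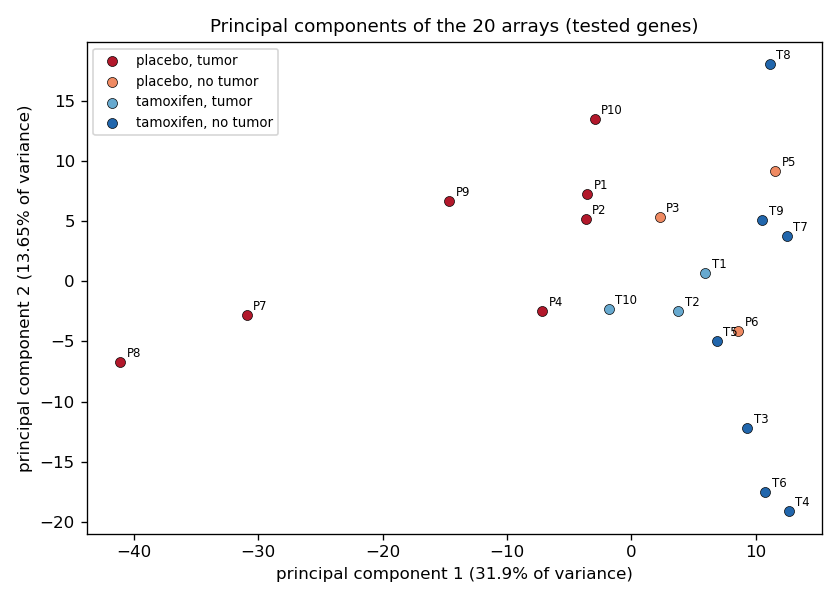
Each point is 1 array on the first and second principal components of the tested genes' log2 values (share of variance in percent on each axis), with colors for treatment and later outcome. Placebo animals 7, 8 and 9 stand apart on the first component, at -30.94, -41.13 and -14.64.

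The outcome comparison asked how glands of animals that later had tumors differed from glands of animals that did not. Milk protein genes were higher in the animals with later tumors. Csn1s1 (Entrez ID 12990), which encodes an alpha-casein of milk, averaged 11.60 ± 2.00 (SD, n = 10) on the log2 scale with a later tumor and 7.45 ± 0.58 (SD, n = 10) without, a 17.8-fold rise. Csn2 (Entrez ID 12991), the beta-casein gene, averaged 11.77 ± 2.81 against 6.46 ± 1.33, a 39.7-fold rise (SD, n = 10 each). Its mean without a tumor lay below the filter level of 6.85, so the size of that fold is uncertain. Elf5, a transcription factor of alveolar and luminal progenitor cells, rose 3.28-fold, from 8.31 ± 0.56 to 10.02 ± 1.08 (SD, n = 10 each).

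Csn1s1 and Csn2 are neighbors on mouse chromosome 5 of the GRCm38 assembly, at 87666208 to 87682578 and 87692619 to 87699429. limma called 29 genes for the outcome, 25 up and 4 down in animals with later tumors, and the smallest adjusted p was 0.0123. Csn1s1 (adjusted p = 0.0123), Csn2 and Csn1s2a, another casein gene (both adjusted p = 0.0239), were above the no-tumor median in 9 of 10 animals with later tumors. Csn1s2a rose 38.9-fold, and Btn1a1, a protein of the milk fat globule membrane, rose 2.9-fold with 9 of 10 animals above (adjusted p = 0.0456). Elf5 (adjusted p = 0.0456), Csn3, the kappa-casein gene (2.84-fold, 0.0246), and Lcn2, an iron-siderophore binding protein (2.57-fold, 0.043), rose with all 10 animals above. Also up with 10 of 10 animals above were Cxcl15, a chemokine (4.08-fold, adjusted p = 0.0239), and Tph1, an enzyme of serotonin synthesis (3.38-fold, 0.0476). So were Aldoc, a glycolytic aldolase (1.92-fold, 0.043), Postn, the matrix protein periostin (1.75-fold, 0.0456), and Hmcn1, a matrix protein (1.68-fold, 0.0246). The 4 genes that fell were Mreg (1.88-fold, adjusted p = 0.0246), Ccl22, a chemokine that attracts T cells (1.55-fold, 0.0237), Nudt17 (1.24-fold, 0.0456) and Glud1, a mitochondrial glutamate dehydrogenase (1.19-fold, 0.0476), with 0 of 10 animals above the no-tumor median for each. The no-tumor means of Csn2, Csn1s2a, Tph1 and Hmcn1 lay below the filter level of 6.85, so the sizes of their folds are uncertain. Other probe sets that passed the filter, but averaged below that level over the 20 arrays, rose less on the log2 scale. Their differences were 0.56 for Elf5 (mean 6.47), 0.91 for Cxcl15 (6.79), 0.80 for Csn3 (6.60) and 1.43 for Csn1s2a (5.20). A further probe set was nearer in size to the one used for Csn2 (4.33), Csn1s2a (5.39) and Glud1 (-0.225).

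Among the epithelial lists, milk and alveolar genes rose by a mean of 1.89 on the log2 scale (3.71-fold), and luminal progenitor genes rose by 0.77 (both permutation adjusted p = 0.00075). Of 11 milk and alveolar genes tested, 4 rose over all genes and 9 adjusted over the list alone. Of 15 luminal progenitor genes tested, 3 rose over all genes (Elf5, Csn3 and Lcn2) and 9 adjusted over the list alone, while Plet1 differed by 1.53 (adjusted p = 0.0528) and Kit, a receptor tyrosine kinase, by 0.46 (0.155). Aldh1a3 of this list, given below, did not pass either. Csn3 is itself a casein gene and Elf5 is also a factor of alveolar cells. Whether this list rose apart from the milk and alveolar genes was not tested. For both lists camera gave adjusted p = 0.0669 with an estimated correlation. Pan-epithelial and luminal keratin genes rose by 0.65 (permutation adjusted p = 0.00525), with 0 of 15 members past limma's threshold over all genes and 11 up adjusted over the list alone, and with adjusted p = 0.14 with an estimated correlation. Their largest members were Epcam, an epithelial adhesion molecule (2.05-fold, adjusted p = 0.0528), and the keratin gene Krt19 (2.03-fold, 0.0616). Whether luminal progenitor genes rose by more than pan-epithelial genes (0.77 against 0.65) was not tested. Without placebo animals 7, 8 and 9, a fit chosen after seeing the data, the pan-epithelial difference was 0.39 and did not pass (permutation adjusted p = 0.0638), while milk and alveolar genes differed by 1.42 and luminal progenitor genes by 0.49 (permutation adjusted p = 0.00707 each). With the pan-epithelial list mean as a covariate, a fit chosen after seeing the data, Csn1s1 differed by 2.37 ± 0.58 (SE) instead of 4.15 ± 0.61, and its adjusted p went from 0.0123 to 0.98. Csn2, Csn1s2a and Btn1a1 had the same adjusted p of 0.98, which draws on the p-values of all genes.

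The EGF receptor family and ligands list rose by 0.14 (permutation adjusted p = 0.0356), with 0 of 5 members past limma's threshold over all genes and 2 up adjusted over the list alone. Without placebo animals 7, 8 and 9, a fit chosen after seeing the data, its difference was 0.05 (permutation adjusted p = 0.2). The call was also lost without placebo animal 5, 6, 7 or 8 or tamoxifen animal 4 or 7 (differences 0.12 to 0.14, permutation adjusted p from 0.0514 to 0.07). Tgfa itself averaged 8.99 ± 0.79 against 7.88 ± 0.16 (SD, n = 10 each), a 2.16-fold difference in 10 of 10 animals that did not pass (adjusted p = 0.052). Tgfa was highest in placebo animals 7, 8 and 9 (10.01, 9.99 and 10.27), and without them it differed by 0.64 and passed (adjusted p = 0.0271). Whether this probe set reads the transgene is not given in the sources used here. Erbb3, an EGF receptor relative, differed by 0.57 (adjusted p = 0.125). Cell division genes rose by 0.53 (permutation adjusted p = 0.04), with 0 of 10 past the threshold by either count, and Mki67, a marker of dividing cells, differed by 0.79 (adjusted p = 0.228). Placebo animal 8 had the highest cell division list value, 2.29 against at most 0.51 in the other animals with later tumors, and without that animal the list differed by 0.30 and did not pass (permutation adjusted p = 0.0737). Leaving out placebo animal 3, 5, 6, 7, 9 or 10 or tamoxifen animal 4, 7, 8, 9 or 10 also ended the call, with differences of 0.49 to 0.56. Fibroblast and matrix genes rose by 0.24 (permutation adjusted p = 0.0433), with 1 of 12 up over all genes (Postn) and 5 adjusted over the list alone. With an estimated correlation, camera gave adjusted p = 0.14 for the EGF receptor and the fibroblast lists and 0.251 for cell division.

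T cell genes fell by 0.43 (permutation adjusted p = 0.04), with 0 of 9 past limma's threshold over all genes and 9 down adjusted over the list alone. Among them Ccr7, a homing receptor of lymphocytes, differed by -0.58 (adjusted p = 0.0947), and Cd3e, a T cell receptor subunit, by -0.28 (0.137). The T cell and B cell lists were planned as lymph node lists. Whether the amount of lymph node in the sampled glands differed between any of the groups was not tested. Schwann cell genes fell by 0.20 and circadian clock genes by 0.13 (both permutation adjusted p = 0.04), with 0 of 3 and 0 of 10 members past the threshold by either count. For these 3 lists camera gave adjusted p = 0.14 with an estimated correlation. Their calls and that of the fibroblast list ended without placebo animals 7, 8 and 9, a fit chosen after seeing the data. Only milk and alveolar and luminal progenitor genes passed in it. Leaving out placebo animal 5, 6, 7 or 8 alone left 3 of the 9 outcome lists or others passing. Within treatments, a test chosen after seeing the data, 7 of the 9 outcome lists no longer passed, though each difference kept its direction. Pan-epithelial genes then differed by 0.55 (permutation adjusted p = 0.0515) and cell division genes by 0.51 (0.154). EGF receptor family genes differed by 0.11, fibroblast and matrix genes by 0.22, T cell genes by -0.31, Schwann cell genes by -0.18 and circadian clock genes by -0.12 (permutation adjusted p = 0.129 each). The other 16 lists did not pass. Differences were 0.35 for basal and myoepithelial genes (permutation adjusted p = 0.0638), 0.28 for plasma cell genes (0.0618), 0.17 for oestrogen and progesterone response genes (0.107) and 0.15 for mature luminal genes (0.165). They were -0.15 for white adipocyte genes (0.154), -0.42 for brown adipocyte genes (0.165), 0.16 for fatty acid synthesis genes (0.165) and -0.99 for skeletal muscle genes (0.165) by the same permutation test. B cell genes differed by -0.18 (permutation adjusted p = 0.397), endothelial genes by -0.04 (0.664) and blood genes by 0.06 (0.838). For macrophage, interferon response, epidermis, immediate early and p53 target genes the differences were 0.03, 0.02, 0.02, -0.02 and -9e-04, with permutation adjusted p of 0.915, 0.951, 0.915, 0.915 and 0.98.

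**Figure D2:**
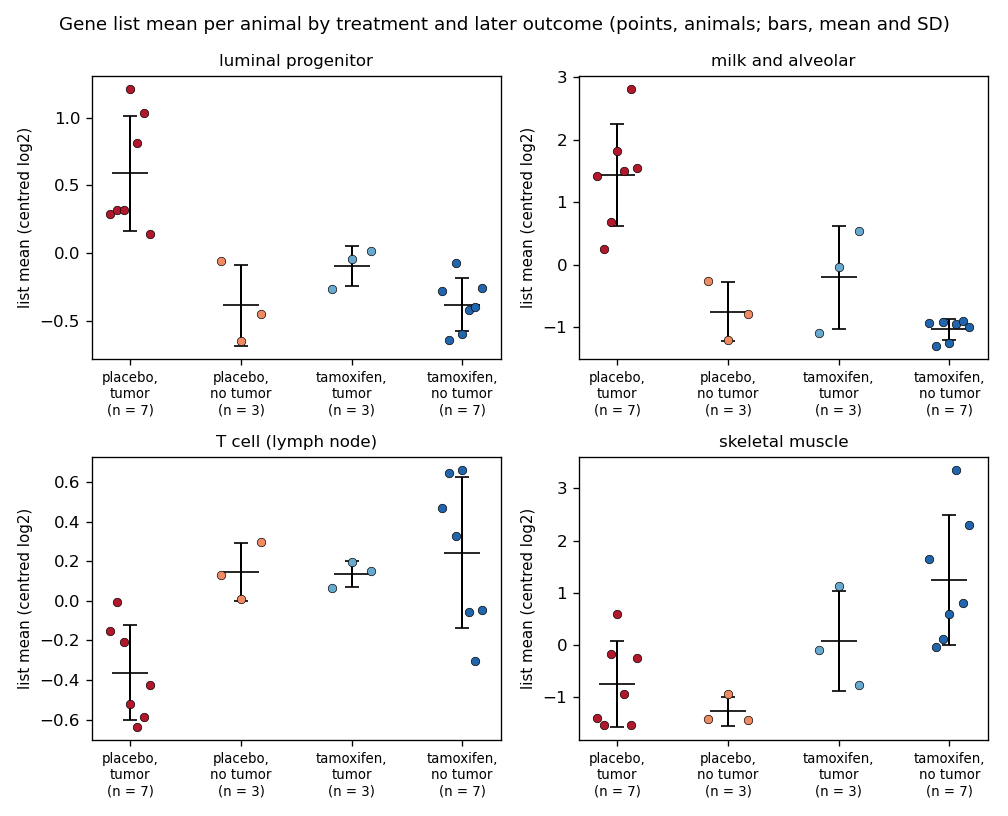
Each point is 1 animal's mean of the gene-wise centred log2 values of the luminal progenitor, milk and alveolar, T cell and skeletal muscle lists, by treatment and later outcome, with bars for the group mean and SD. Milk and alveolar genes averaged 1.89 higher with a later tumor, and skeletal muscle genes averaged 1.80 higher with tamoxifen.

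Esr1, the oestrogen receptor gene, differed by 0.26 between outcomes (adjusted p = 0.357), and Pgr, the progesterone receptor gene, by -0.09 (0.889). Krt18, a luminal keratin, differed by 0.81 (adjusted p = 0.062) and Krt14, a basal keratin, by 0.58 (0.232). Aldh1a3, an aldehyde dehydrogenase of the luminal progenitor list, differed by 0.09 (adjusted p = 0.734). Adipoq, the adiponectin gene of fat cells, differed by -0.06 (adjusted p = 0.595) and Ckm, the muscle creatine kinase gene, by -1.04 (0.392).

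Csn1s1 missed the threshold without moderation of the variances (adjusted p = 0.0664) and with the skeletal muscle list mean as a covariate (3.98 on the log2 scale, adjusted p = 0.0923), the latter chosen after seeing the data. Leaving out 1 animal gave from 1 gene (without placebo animal 5 or tamoxifen animal 6, 7 or 9) to 118 genes (without tamoxifen animal 1), and without placebo animals 7, 8 and 9, a fit chosen after seeing the data, limma called 8, of which 2 were among the 29.

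The treatment comparison asked how glands differed between treatments 4 weeks after tamoxifen had ended. Akr1cl (Entrez ID 70861), an aldo-keto reductase family member, averaged 10.89 ± 1.49 (SD, n = 10) with tamoxifen and 8.01 ± 0.38 (SD, n = 10) with placebo. It rose 7.36-fold and was the only gene that limma called, with 10 of 10 tamoxifen animals above the placebo median (adjusted p = 0.0319). Skeletal muscle genes rose by 1.80 on the log2 scale (3.49-fold, permutation adjusted p = 0.018) and milk and alveolar genes fell by 1.56 (2.95-fold, 0.0344). With an estimated correlation, camera gave adjusted p = 0.241 for both lists.

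Akr1cl lies on chromosome 1 of the GRCm38 assembly, at 65013078 to 65032759. At an unadjusted level of 0.05, 1739 genes differed between treatments. All 12 skeletal muscle genes tested were up adjusted over the list alone and 0 passed limma over all genes. Tnnc2, a troponin of fast muscle, differed 8.69-fold and Acta1, skeletal muscle actin, 7.28-fold (both adjusted p = 0.0706), the former from a placebo mean of 6.58, below the filter level of 6.85, and Ckm differed 3.82-fold (0.119). Of 11 milk and alveolar genes, 0 passed limma over all genes and 7 were down adjusted over the list alone, with Csn2 at -4.34 (adjusted p = 0.129). Luminal progenitor genes differed by -0.59 and T cell genes by 0.42, and neither list passed (both permutation adjusted p = 0.0615). For p53 targets and interferon response genes, which did not pass either, the mean and the median of the members differed in sign.

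The next genes by p, all at adjusted p = 0.0554, did not pass. Arg2, an arginase, differed by -1.22, Prtn3, a neutrophil serine protease, by 2.09, Ampd3 by 0.65, Gpc3, a glypican, by -0.58 and Rhbg, an ammonium transporter, by -0.49. Adgrg6 differed by -0.41, Ppp1r14c by 0.29, Fam174b by -0.29 and Tpst1 by -0.24. Elf5 differed by -1.51 (adjusted p = 0.131), Tgfa by -0.85 (0.187), Krt18 by -0.52 (0.311), Mki67 by -0.34 (0.709) and Esr1 by -0.30 (0.316). Kit differed by -0.28 (adjusted p = 0.49), Pgr by 0.20 (0.734), Aldh1a3 by -0.14 (0.603), Krt14 by -0.13 (0.857) and Adipoq by 0.01 (0.922).

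The Akr1cl call in the treatment comparison was lost without placebo animals 7, 8 and 9 (2.77 on the log2 scale, adjusted p = 0.15) and with the skeletal muscle (2.31, adjusted p = 0.143) or pan-epithelial list mean as a covariate (2.73, adjusted p = 0.197), fits chosen after seeing the data. Among the settings fixed before, it was lost with the mean of all its probe sets (1.94, adjusted p = 0.0503), every probe set tested (0.0557), array weights (2.50, 0.0625, with another gene called, down) and no moderation (0.0701). Leaving out 1 animal gave from 0 genes (without placebo animal 2, 7, 9 or 10 or tamoxifen animal 4, 5, 6, 7 or 9) to 110 genes (without placebo animal 6).

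The groups farthest apart in the design were the tamoxifen animals without tumors and the placebo animals with tumors, 7 each. They differ in both treatment and outcome, so no difference between them can be assigned to either alone. These animals also entered the outcome and treatment comparisons. All 29 outcome genes and the 1 treatment gene were called again here, which is no independent support. The largest falls were in milk protein genes, with Csn2 119-fold, Csn1s2a 105-fold and Csn1s1 35.6-fold lower in the tamoxifen animals without tumors. In those animals Csn2 (6.05) and Csn1s2a (5.35) averaged below the filter level of 6.85, so the sizes of their folds are uncertain. Akr1cl averaged 11.70 ± 0.80 (SD, n = 7) in the tamoxifen animals without tumors. In the placebo animals with tumors it averaged 8.04 ± 0.45 (SD, n = 7), which makes a 12.6-fold rise. Skeletal muscle genes rose 4-fold as a list, luminal progenitor genes fell by 0.97 and T cell genes rose by 0.61 on the log2 scale. For the skeletal muscle and T cell lists camera gave adjusted p = 0.197 with an estimated correlation.

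limma called 579 genes in this comparison, 279 up and 300 down in the tamoxifen animals without tumors. In fits chosen after seeing the data, it called 275 genes without placebo animals 7 and 8 (67 up and 208 down) and 141 without placebo animals 7, 8 and 9 (20 up and 121 down). The 12 largest rises were above the placebo tumor median in 7 of 7 animals and the 12 largest falls in 0 of 7. After Akr1cl (adjusted p = 2.17e-06) the rises included Prtn3 (5.73-fold, adjusted p = 0.000694), Nmu, the neuropeptide neuromedin U (3.96-fold, 0.000358), and Mmd2 (3.37-fold, 0.00937). The other 8 were the muscle genes Tnnc2, Acta1, Tnni2, Tnnt3, Mylpf, Atp2a1, Ckm and Ttn, among them Tnnc2 (9.82-fold, adjusted p = 0.0194) and Acta1 (9.57-fold, 0.0141). Besides Csn2 (adjusted p = 0.000358), Csn1s2a (0.000629) and Csn1s1 (2.67e-05), the falls were Muc15, a mucin of milk fat globules (7.69-fold, 0.00182), Cxcl15 (6.49-fold, 0.000358), Wfdc18 (5.04-fold, 0.012) and Elf5 (4.95-fold, 0.00116). Btn1a1 (4.33-fold, adjusted p = 0.000703), Tph1 (4.22-fold, 0.0119), Plet1 (4.03-fold, 0.00265), Gjb2, a gap junction protein (3.93-fold, 0.0335), and Csn3 (3.85-fold, 0.000759) completed them. Among list members, Tgfa fell 2.64-fold (adjusted p = 0.00304), Postn 2.1-fold (0.000952) and Epcam by 1.31 on the log2 scale (0.00388), and Ccr7 rose 1.7-fold (0.0194). The lower group's mean lay below the filter level of 6.85 for Csn2, Csn1s2a, Cxcl15, Tph1, Gjb2 and Nmu, as for the muscle genes Mylpf, Tnnt3 and Ttn, so the sizes of their folds are uncertain. A second Plet1 probe set above that level differed by -0.05 ± 0.04 (SE) and a second Ckm probe set by 0.18 ± 0.10 (SE). Other probe sets kept the direction with smaller log2 differences for Csn1s2a (-1.99), Elf5 (-0.75), Cxcl15 (-1.22), Csn3 (-1.20), Tnni2 (1.24) and Ttn (0.94). A further probe set was nearer in size to the one used for Csn2 (-5.59), Csn1s2a (-6.88), Mmd2 (2.19) and Plet1 (-1.70).

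By the exact permutation test, 6 lists passed between these groups, 3 without placebo animal 8 or 9, and 2 (milk and alveolar, luminal progenitor) without placebo animals 7, 8 and 9, the last chosen after seeing the data. Milk and alveolar genes (5.52-fold) and luminal progenitor genes fell with exact adjusted p = 0.00728, whose unadjusted exact p of 0.000583 is the smallest that 7 against 7 animals can give. Of the members tested, 7 of 11 and 7 of 15 fell over all genes and 9 and 10 adjusted over the list alone, and both lists held with an estimated correlation (adjusted p = 0.0465). Pan-epithelial genes fell by 0.79 (exact adjusted p = 0.0146, 11 of 15 down over all genes, 12 adjusted over the list alone), with adjusted p = 0.176 with an estimated correlation. EGF receptor family genes fell by 0.18 (exact adjusted p = 0.0437, 2 of 5 down over all genes, 3 adjusted over the list alone), with adjusted p = 0.219 with an estimated correlation. T cell genes (exact adjusted p = 0.032) were up in 8 of 9 over all genes and 9 adjusted over the list alone, and skeletal muscle genes (exact adjusted p = 0.0182) in 7 of 12 and 12. Leaving out 1 animal gave from 295 genes (without tamoxifen animal 4) to 846 genes (without tamoxifen animal 8), and with the pan-epithelial list mean as a covariate, a fit chosen after seeing the data, limma called 6, with Csn1s1 at -3.76 (adjusted p = 0.0246).

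**Figure D3:**
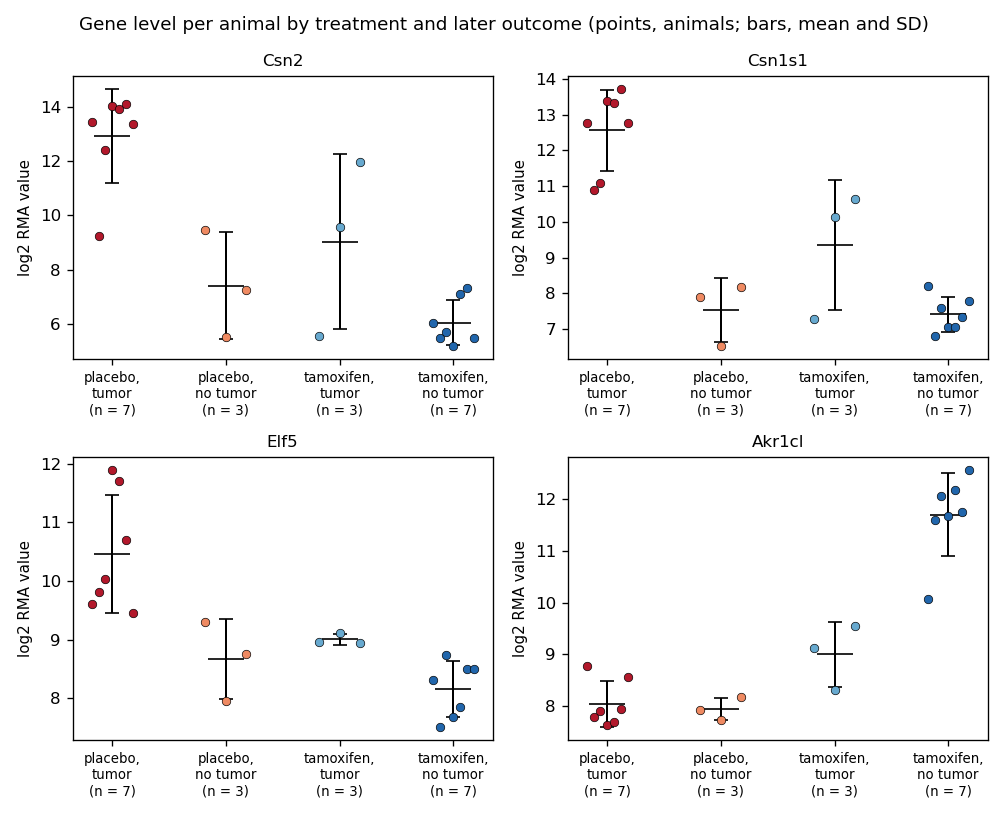
Each point is 1 animal's log2 expression of Csn2, Csn1s1, Elf5 and Akr1cl by treatment and later outcome, with bars for the group mean and SD. Csn1s1 averaged 12.56 in placebo animals with a later tumor and 7.54 in placebo animals without, and Akr1cl averaged 11.70 in tamoxifen animals without a tumor.

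Since treatment and outcome were unequally combined, each was also adjusted for the other. Csn1s1 was 11.2-fold higher with a later tumor after adjustment for treatment, and Akr1cl was 5.13-fold higher with tamoxifen after adjustment for outcome, and neither passed (adjusted p = 0.0703 and 0.16). limma called 0 genes in either fit, with 1149 and 926 genes at an unadjusted p under 0.05. The next genes for outcome were Slc35f3 (0.56, adjusted p = 0.126) and Ccl22 (-0.60, 0.128), and for treatment Gpc3 (-0.51, 0.343) and Arg2 (-0.93, 0.343). Within treatments, a test chosen after seeing the data, milk and alveolar genes were higher with a later tumor by 1.51 and luminal progenitor genes by 0.63 (both permutation adjusted p = 0.00868). Within outcomes, skeletal muscle genes were higher with tamoxifen by 1.67 and milk and alveolar genes differed by -0.95, and neither list passed (both permutation adjusted p = 0.0504).

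The outcome difference was also taken within each treatment. In placebo animals Csn1s1 averaged 12.56 ± 1.13 (SD, n = 7) with a later tumor and 7.54 ± 0.89 (SD, n = 3) without, a 32.6-fold rise seen in 7 of 7 animals, and it was the only gene limma called (adjusted p = 0.00404). In tamoxifen animals Akr1cl averaged 9.0 ± 0.63 (SD, n = 3) with a later tumor and 11.70 ± 0.80 (SD, n = 7) without, a 6.51-fold fall with 0 of 3 above the no-tumor median, and it was the only gene called (adjusted p = 0.0138). In placebo animals Akr1cl averaged 8.04 ± 0.45 (SD, n = 7) with and 7.94 ± 0.22 (SD, n = 3) without a later tumor. The interaction of treatment and outcome, which tests whether these differences differ, called 0 genes in limma, with 565 at an unadjusted p under 0.05. Its leading genes were Gng12, a G protein subunit (-0.85), Akr1cl (-2.80) and Pifo (-0.69), all at adjusted p = 0.26. The Csn1s1 call was lost without placebo animal 5, the Akr1cl call without tamoxifen animal 2, and both without placebo animals 7, 8 and 9 (adjusted p = 0.0517 and 0.0552), a fit chosen after seeing the data. In that fit the differences were 4.34 for Csn1s1 instead of 5.03 and -2.70 for Akr1cl, as before. No tamoxifen animal was left out in that fit. The adjusted p of Akr1cl can still move with the spread shared by the 4 groups, the number of arrays or the adjustment over genes. These were not told apart.

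Across 12498 genes, the outcome differences in placebo animals and those in tamoxifen animals correlated with Pearson r = 0.319 (permutation p = 0.0495, 100 draws, two-sided). Draws of the outcome labels within treatments gave r from -0.39 to 0.38. The call was lost for the Spearman correlation, 0.22 (permutation p = 0.257), with the 75th percentile filter (r = 0.316, permutation p = 0.0693) and with the mean of each run of numbers removed (r = 0.441, permutation p = 0.0594). It was also lost in 9 of 20 fits that left out 1 animal (placebo 1 or 2, or tamoxifen 1, 2, 3, 4, 8, 9 or 10), with r down to 0.213 without tamoxifen animal 10. Genes are not independent replicates.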

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

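The tests of explanations in this part, and the list tests within treatments and outcomes, were chosen only after the result was seen. Of 178 groups of values tested for a single animal far from the others, 15 held one. The rule's nominal rate is about 1 in 20 for normal values. The groups shared animals, and the chance rate in these data was not measured. The number given for each is the animal's gap to its nearest neighbor as a share of the group's range.

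Milk protein genes were higher in animals with later tumors, and the milk and alveolar list differed by 1.89 on the log2 scale. To test more epithelium in the sampled gland as the whole cause, the pan-epithelial list mean was subtracted. The milk minus pan-epithelial list mean was still higher by 1.244 (permutation p = 0.00017). This cannot exclude that cause, since it takes both lists to rise equally on the log2 scale with epithelium. Their members differed in range over the animals, with Csn2 from 5.18 to 14.13 and Epcam from 9.58 to 12.33. With the pan-epithelial list mean as a covariate, Csn1s1 went from 4.15 ± 0.61 (SE) to 2.37 ± 0.58, so part of the difference may go with the amount of epithelium. Its limma call ended (adjusted p = 0.98). Csn2, Csn1s2a and Btn1a1 had the same adjusted p, which draws on the p-values of all genes. It does not show that the difference in Csn1s1 was gone. The list difference was 1.421 without placebo animals 7, 8 and 9 (permutation p = 0.000463) and 1.51 within treatments (permutation p = 0.000417), which argues against those animals or the unequal treatment as the whole cause. More epithelium stays open, and so does a biological difference tied to the later outcome, which was not tested.

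Skeletal muscle genes were higher with tamoxifen by 1.80, and 0 of the list's 13 genes were in another list. Among the abundant ones, Acta1 averaged 11.28 ± 1.47 (SD, n = 10) with tamoxifen and 8.42 ± 1.49 (SD, n = 10) with placebo, and the labels name no step that would remove muscle. The first principal component held 90.9% of the members' variance over the 20 animals, which is consistent with muscle tissue taken with the gland in unequal amounts. The smaller of the differences in animals numbered 1 to 5 and 6 to 10 was 1.638 and both had the same sign (exact p = 0.00794 and 0.0397), which argues against a dissection that differed in 1 run of numbers only. Within outcomes the difference was 1.675 (permutation p = 0.00375), so an effect of tamoxifen itself cannot be told apart from muscle taken with the gland, because either would raise all these genes together.

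Cell division genes were highest in placebo animal 8, at 2.29 for the list against at most 0.51 in the other animals with later tumors (share 0.675), and 12 of 13 members were highest there. For more epithelium in that gland, the cell division minus pan-epithelial list mean was 1.214 there and at most 0.574 in the other animals. This cannot decide the question, since the animal was picked for its high cell division value. Its pan-epithelial list mean of 1.078 was close to that of placebo animal 7 (1.065), whose cell division value was 0.508. Lymphocytes are argued against by ranks of 13 and 20 among 20 animals for the B cell and T cell lists. No biological explanation was tested.

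Among animals without tumors, placebo animal 3 was highest for Csn2 (9.45, next 7.32, share 0.5), Csn1s2a (7.79, next 6.02, share 0.609) and the milk and alveolar list (-0.26, next -0.78, share 0.498). Among placebo animals with tumors, animal 2 was lowest for Csn2 (9.23, next 12.43, share 0.653). Placebo animal 8 was highest for Mki67 among animals with tumors (10.77, next 8.71, share 0.556) and among placebo animals (share 0.534), and lowest of the placebo animals for Aldh1a3 (7.66, next 8.17, share 0.59). Placebo animal 7 was highest among animals with tumors for Hmcn1 (8.05, next 7.37, share 0.652) and Kit (10.38, next 9.52, share 0.518). Tamoxifen animal 8 was lowest for Hmcn1 among animals without tumors (5.71, next 6.36, share 0.547). Tamoxifen animal 5 was the lowest tamoxifen animal for Tpst1 (9.38, next 9.56, share 0.506). Placebo animal 5 was the lowest placebo animal for Krt18 (9.44, next 10.56, share 0.519). Among tamoxifen animals without tumors, animal 3 was lowest for Akr1cl (10.06, next 11.6, share 0.613) and Prtn3 (8.76, next 10.37, share 0.731).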

How the results depend on the processing

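The fits without placebo animals 7 and 8 (with or without animal 9), the fits with a covariate, and the list tests within treatments or outcomes were chosen only after the result was seen; the other alternatives were planned. Where no cause is named, the cause was not tested. Over 12 main results, 102 alternative values stayed on the same side of the threshold or within 1.5 times the count, 56 counts moved beyond that and 3 values lost their call. Quantile normalization again, trend and robust settings, and leaving out probe sets with an _x_at ending moved none of the 8 gene counts past that bound. For named genes, outside the fits that left out 1 animal, 1090 values kept direction and side of the threshold, 175 fell below it, 25 rose past it and 24 changed sign. For the lists that had passed, 57 values fell below it and 0 changed sign, and other lists rose past it under some settings. The filter's level of 6.85 is the median of all values, so differences in dim genes are poorly measured.

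The 29 genes for tumor against no tumor became 11 with arrays centred on their median, 14 with no filter, 0 with t statistics without moderation, 45 with a block for the 2 runs of numbers, 8 without placebo animals 7, 8 and 9, 0 with the muscle covariate and 1 with the pan-epithelial covariate. The 1 gene for tamoxifen against placebo became 2 with no filter and 4 with the 75th percentile filter, and 0 with the mean of probe sets, every probe set tested, no moderation, without placebo animals 7 and 8, without 7, 8 and 9, and with the muscle covariate. With array weights or the pan-epithelial covariate it was again 1 gene, but not Akr1cl (adjusted p = 0.0625 and 0.197). The 0 genes for outcome adjusted for treatment became 1 with the 75th percentile filter or every probe set and 6 with the block for runs of numbers. The 0 for treatment adjusted for outcome became 1 with no filter or the muscle covariate and 2 with the pan-epithelial covariate. The 1 gene in placebo animals became 2 with the mean of probe sets and 0 without placebo animals 7, 8 and 9 or with the pan-epithelial covariate. The 1 gene in tamoxifen animals became 13 with array weights and 0 without moderation, without placebo animals 7, 8 and 9 and with the muscle covariate, where Akr1cl differed by -2.76 (adjusted p = 0.0563) against -2.70 before. The interaction went from 0 to 1 with array weights. The 579 genes between the 7-animal groups became 353 with the 75th percentile filter, 895 with every probe set, 356 without moderation, 275 without placebo animals 7 and 8, 141 without 7, 8 and 9 (20 up and 121 down), and 6 with the pan-epithelial covariate.

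With a replicate block the counts were 35 for outcome, 235 for treatment, 1 for treatment adjusted for outcome, 602 in placebo animals, 5 in tamoxifen animals, 2 for the interaction and 1647 between the 7-animal groups, and 3 lists passed for outcome. Pairing by number was not shown: 4 of 10 pairs had r over 0.1 in either numbering, with r from -0.11 to 0.46 within treatment numbers and -0.17 to 0.33 within outcome numbers. Of 20 animals, 4 correlated best with their own treatment number and 1 with its own outcome number. What unrelated animals would give was not measured, so pairing is not excluded. Whether the replicate block is a correction here therefore cannot be told. For lists between the 7-animal groups the replicate block was not run, as pairs were incomplete.

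Lists passing for outcome went from 9 to 18 with camera at a preset correlation, 0 with an estimated correlation, 3 without placebo animals 7 and 8, and 2 without 7, 8 and 9 or within treatments. For treatment they went from 2 to 9, 0, 1 and 1, to 5 with members that pass the filter, and to 0 within outcomes. Between the 7-animal groups they went from 6 to 12 with the preset and 2 with the estimated correlation, and 2 without placebo animals 7, 8 and 9. The correlation of outcome effects lost its call with the 75th percentile filter (0.316), as Spearman's (0.22) and with the mean of each run of numbers removed (0.441).

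Leaving out 1 animal gave 1 to 118 genes for outcome: 1 without placebo 5 or tamoxifen 6, 7 or 9, 3 without tamoxifen 4, 6 without placebo 8, 7 without placebo 1, 8 without tamoxifen 3, 9 without tamoxifen 8, 10 without placebo 4 or 9, 12 without placebo 2, 14 without tamoxifen 5, 81 without tamoxifen 10, 84 without placebo 3, 94 without tamoxifen 2 and 118 without tamoxifen 1. For treatment it gave 0 to 110: 0 without placebo 2, 7, 9 or 10 or tamoxifen 4, 5, 6, 7 or 9, 2 without placebo 4 or tamoxifen 8, 3 without placebo 3, 4 without placebo 8, 22 without tamoxifen 2, 30 without tamoxifen 10, 59 without placebo 5 and 110 without placebo 6. Adjusted, outcome gave 0 to 6 (4 without placebo 2, 6 without tamoxifen 1) and treatment 0 to 2 (2 without tamoxifen 2). In placebo animals the range was 0 to 60 (0 without placebo 5, 2 without 8, 5 without 2, 10 without 6, 60 without 10), in tamoxifen animals 0 to 7 (0 without tamoxifen 2, 2 without 6, 3 without 4, 7 without 3), and for the interaction 0 to 3 (3 without tamoxifen 3). Between the 7-animal groups it was 295 to 846, with 295, 339, 340 and 352 without tamoxifen 4, 3, 6 and 5, and 310, 327 and 383 without placebo 7, 8 and 9.

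Lists passing ranged from 3 to 11 for outcome (3 without placebo 5, 6, 7 or 8, 4 without placebo 10 or tamoxifen 7, 5 without placebo 9 or tamoxifen 4 or 10), and from 1 to 5 for treatment (1 without placebo 1, 4, 7, 8, 9 or 10 or tamoxifen 1, 3, 4, 5, 6, 7 or 9, 4 without placebo 3 or 6, 5 without placebo 5). They ranged from 3 to 7 between the 7-animal groups (3 without placebo 8 or 9). The correlation ranged from 0.213 (without tamoxifen 10) to 0.343 (without tamoxifen 9) and did not pass without placebo 1 or 2 or tamoxifen 1, 2, 3, 4, 8, 9 or 10.

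Differences that had not passed changed sign. For outcome, Pgr was 0.0368 and Adipoq 1e-04 without placebo animals 7 and 8, Pgr was 0.0193 without 7, 8 and 9, Ckm was 0.0662 with the muscle covariate, and Krt14 was -0.1792 and Adipoq 0.0318 with the pan-epithelial covariate. For treatment, Krt14, Mki67 and Adipoq were 0.1119, 0.1395 and -0.0226 with array weights, 0.2148, 0.0946 and -0.0462 without placebo animals 7 and 8, and 0.2897, 0.2186 and -0.0425 without 7, 8 and 9. With the pan-epithelial covariate they were 0.4426, 0.259 and -0.0474, and Kit was 0.0499, and with the muscle covariate Ckm was -0.0918. Leaving out 1 animal, Pgr ranged from -0.2041 to 0.0077 for outcome, and for treatment Krt14 ranged from -0.2489 to 0.0552 and Adipoq from -0.0167 to 0.0302. Between the 7-animal groups the called Tnni2, Tnnt3, Ckm and Ttn were -0.0865, -0.1001, -0.1062 and -0.1739 with the muscle covariate, which by construction removes what follows the muscle list.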

Other observations

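The list tests within placebo and tamoxifen animals were chosen only after the result was seen, and the splits of the samples were planned. Within placebo animals, milk and alveolar genes were higher with a later tumor by 2.18 (exact p = 0.00833, the smallest that 7 against 3 animals can give), luminal progenitor genes by 0.98 (exact p = 0.0167) and oestrogen and progesterone response genes by 0.40 (exact p = 0.0167). Circadian clock genes differed by -0.17 (exact p = 0.00833, also the smallest possible). Pan-epithelial genes differed by 0.92, EGF receptor family genes by 0.22, T cell genes by -0.51 and brown adipocyte genes by -0.85 (exact p = 0.0167 each), and basal and myoepithelial genes by 0.70 (exact p = 0.0333). Within tamoxifen animals the differences were 0.84 for milk and alveolar genes (exact p = 0.05), 0.28 for luminal progenitor genes (exact p = 0.0667), -0.06 for oestrogen and progesterone response genes (exact p = 0.442), -0.01 for brown adipocyte genes (exact p = 1) and -0.06 for basal and myoepithelial genes (exact p = 0.725). Over the 25 lists none passed in either treatment, and the smallest adjusted exact p was 0.0521 in placebo and 0.781 in tamoxifen animals. The difference between treatments in these outcome differences passed for no list, and the smallest adjusted permutation p was 0.274, for oestrogen and progesterone response genes (-0.46).

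For each gene-wise comparison, 100 splits of the animals into groups of the same sizes, the real one included, were fitted with limma. Between tamoxifen animals without tumors and placebo animals with tumors, 1 of 100 splits, the real one, gave 579 genes (highest other 372). At an unadjusted p under 0.05 the real split gave 2548 genes, and 3 of 100 splits gave as many (highest other 2575). Chance is therefore unlikely for the 579 genes called but not excluded. For tumor against no tumor 2 of 100 splits gave 29 genes or more, and the highest other gave 255. These splits moved the outcome labels across treatments, and the fit adjusted for treatment, given below, did not exclude chance. Chance is therefore unlikely for this count but not excluded. For outcome within tamoxifen animals 4 of 100 splits gave the 1 gene called or more (highest other 263). At an unadjusted p under 0.05 the real split gave 262 genes, fewer than the 624.9 expected by chance, and 56 of 100 splits gave as many. Chance is therefore not excluded there. For tumor against no tumor and for outcome within tamoxifen animals, another split called several times the real count. What set those splits apart was not tested. Chance cannot be excluded for tamoxifen against placebo (5 of 100 splits, 1 gene, highest other 30), although at an unadjusted p under 0.05 the real split gave 1739 genes and 4 of 100 splits gave as many (highest other 2127). It cannot be excluded either for outcome within placebo animals (14 of 100 splits, 1 gene, highest other 1521). Counted at an unadjusted p under 0.05, it cannot be excluded for outcome adjusted for treatment (12 of 100 splits, 1149 genes, highest other 1920). The same held for treatment adjusted for outcome (25 of 100 splits, 926 genes, highest other 3109) and the interaction (33 of 100 splits, 565 genes, highest other 3312).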
